A study of Rattus norvegicus with 48 samples.

How the data were processed

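The measurements were quantitative RT-PCR assays of neurons collected from rat brainstem sections by laser capture microdissection. Per the labels, neurons were chosen by fluorescent staining for Rbfox3, a neuronal nuclear protein, with DAPI marking their nuclei, so the level of Rbfox3 is not read as a finding between groups. Each sample was a pool of 6 to 20 such cells from a Spontaneously Hypertensive Rat (SHR) or a Wistar Kyoto rat (WKY). The region of each pool was taken from its source name, NTS (nucleus of the solitary tract) or RVLM (rostral ventrolateral medulla), although the titles and the extraction protocol speak of the NTS alone. There were 48 pools, of which 16 were SHR NTS, 17 WKY NTS, 8 SHR RVLM and 7 WKY RVLM. The protocol also describes brain injections of locked nucleic acid inhibitors of miR-135a and miR-376a, but no treatment label stands on these samples and no treatment was compared.

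Per the labels' protocols, the reactions ran for 30 cycles on Fluidigm BioMark arrays with EvaGreen dye and intron-spanning primers, and threshold cycles (Ct) came from the Fluidigm Real-Time PCR Analysis Software. The deposited normalized values are on a log2 scale if each PCR cycle doubles the product, since each equals a constant of the pool minus the Ct, and a higher value means more RNA. How they were normalized is not given in the sources used here and was worked out from the files. For the 92 mRNA assays the constant was the pool's median Ct over its detected mRNA assays in 44 of 44 pools with a usable raw Ct, within 1e-06 cycles. For the 3 microRNA assays it was another constant, lower by 2.83 to 6.58 cycles (median 4.02) in 41 pools and equal to the mRNA median in 3 pools (SHR NTS pool 14 and WKY NTS pools 14 and 15). The origin of this microRNA constant is unknown, so a microRNA difference also holds any difference in that constant.

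The deposited raw table has 48 names over 49 columns of Ct values. The raw Ct of 44 pools was used, which left 3 WKY RVLM pools with a raw Ct. The other 5 columns were not used here: 1 matches no normalized column, and 4, with 44 to 82 values, each match 1 normalized column by a single constant but stand under another name. Columns were not given to pools by their values. These 4 columns held 71, 44, 82 and 78 values, as many as the assays detected in WKY RVLM pools 5, 6, 7 and 8, so they most likely hold those pools. Their median Ct was 14.2 to 16.7, earlier than in the 3 WKY RVLM pools used. Every raw Ct result for WKY RVLM thus rests on 3 pools that most likely had the latest Ct of their group. Of all normalized values 735 (16.1%) were missing, and 3 raw values lay above the 30 cycles of the protocol, so they cannot be levels measured within that run: miR-376a in WKY RVLM pool 2 (Ct 38.91), miR-135a in WKY NTS pool 12 (34.46) and miR7b in WKY NTS pool 8 (30.88). They stayed in the planned fit as deposited, and an alternative counts them as undetected. Assays kept the names of the files, and a gene table of assembly GRCr8 gave the symbol of the accession, which was equal for 90 of the 95 assays. The assay named miR7b carries an accession that this table lists as Mir9, so its identity is uncertain. Rbfox3 was measured by 2 assays, A048 and A073.

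WKY NTS pools 14 and 15 were much closer to each other than other pools of a group. The robust SD of their difference was 0.230 cycles (SD 0.302) over 92 assays, against at least 0.623 (median 1.86) among the other within-group pairs. Between the 2 Rbfox3 assays, which measure the same transcript, it was 0.148 (SD 0.541) over 45 pools. The values of both pools were therefore averaged and counted as 1 sample, which gave 47 samples. This departs from the planned fit of all 48 pools and was decided after the data were seen. With all 48 pools counted, the numbers of assays past the threshold were the same in 4 of the 5 comparisons, but 5 in place of 2 between the regions of SHR, and both numbers are given there.

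Each assay was fitted by least squares with 1 mean per group of strain and region, and its variance was moderated with limma's squeezeVar, which gave the p-values of lmFit and eBayes within 3.3e-16. An assay was tested where each group of the comparison had at least 3 values. Tests were two-sided, with Benjamini-Hochberg adjustment over the assays tested and a threshold of 0.05. The comparisons were SHR against WKY in each region, the difference between these strain differences, and NTS against RVLM in each strain. Undetected values stayed missing. Each assay was also compared by permuting the group labels, exactly where the number of splits was small enough, otherwise with 100000 resamples. Detection in each pool was compared by Fisher's exact test.

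The comparisons, the tests, the gene lists and the rule for named assays were set before the data were examined. The rule named up to 25 assays past the threshold or, where fewer than 10 passed, the 10 with the smallest p, always with miR-135a, miR-376a, Rbfox3 and Th, and in each list up to 4 members with the smallest p. The lists with members on the panel were the study microRNAs, all microRNAs, catecholamine synthesis, glutamate transmission, GABA and glycine transmission, neuropeptides and their receptors, the renin-angiotensin-aldosterone system, immediate early genes, inflammation with leukotrienes and prostaglandins, oxidative stress and nitric oxide, ion channels, kinases and second messengers, and neuron, astrocyte, microglia and reference markers. The panel held 0 members of the lists for adrenergic receptors, cholinergic and serotonergic genes, oligodendrocytes, endothelial and mural cells and microRNA processing. A list's shift was the mean over its members of values centred on the assay mean, for members with a value in at least 80% of pools and lists of 3 or more such members, compared by a permutation test of the strain labels within region.

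Series text gives 4 to 5 animals per group, and the labels tie no pool to an animal. Pools therefore share animals, no animal term could be fitted, and p-values over pools are too small. The number of molecules behind a Ct is unknown, so precision was judged from the spread between pools. In data simulated on the spread of these pools with 20 assays shifted by 4 log2 units, the test recovered 83.3% of them for the strains in the NTS, 55.9% for the strains in the RVLM, 35.8% for the difference of strain differences, 65.9% between the regions of WKY and 73.1% between those of SHR. With a shift of 2 log2 units these shares were 28.1%, 7.6%, 3.9%, 10.3% and 14.2%. The simulated pools were independent, and each assay had the same spread in every group. Real pools share animals and their spread differed between groups, so these shares may be too high.

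Alternatives set in advance changed the scaling (centring on assays detected in every pool, no normalization, Actb as reference, microRNAs on their own median), the handling of undetected values, the cell number, the pools in the fit, the variance model, the filter and the replicate number as a block. Others were chosen after seeing the data: only pools with at least 60 assays detected, the number of assays detected or the median mRNA Ct as a covariate, microRNAs relative to the mRNA median, a Ct above the last cycle counted as undetected, and alternative treatments of the close pools. With the median mRNA Ct as a covariate the filter of 3 values also counted pools without a raw Ct. Some assays were thus tested on fewer than 3 WKY RVLM pools (73 tested between the strains in the RVLM, against 49 without normalization). Counts of that setting are not given where WKY RVLM was compared. Computation used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and matplotlib for the plots. The results of 1 assay that the rule named are not reported here, and it stayed in every fit and adjustment. Correlations between assays across pools were not computed, because the pools are not independent.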

Results

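Small pools of brainstem neurons from hypertensive SHR and normotensive WKY rats were assayed for 92 mRNAs and 3 microRNAs. The pools came from the NTS, which receives the baroreceptor afferents, and from the RVLM, whose neurons drive sympathetic vasomotor tone. There were 16 SHR NTS pools, 17 WKY NTS pools, 8 SHR RVLM pools and 7 WKY RVLM pools. WKY NTS pools 14 and 15 had nearly the same values (SD of their difference 0.302 cycles, against 0.541 between the 2 assays of Rbfox3 over 45 pools; by a robust SD, 0.230 against 0.148). They differed by less than the 2 Rbfox3 assays in the first measure and by more in the second. Both pools were counted as 1 sample, so that 47 samples were compared. Levels are given in log2 units relative to the median mRNA of the pool, or for microRNAs relative to the constant used for them in the deposited values.

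Pools held 12.9 ± 3.20 cells in SHR NTS (SD, n = 16), 11.6 ± 1.85 in WKY NTS (n = 16), 10.25 ± 2.05 in SHR RVLM (n = 8) and 9.86 ± 0.900 in WKY RVLM (n = 7). Of the 95 assays, 85.25 ± 10.1 were detected per pool in SHR NTS, 78.7 ± 16.1 in WKY NTS, 80.1 ± 10.9 in SHR RVLM and 66.6 ± 13.5 in WKY RVLM. The median mRNA Ct, which falls with more RNA, was 12.5 ± 2.38 in SHR NTS (n = 16), 14.1 ± 2.99 in WKY NTS (n = 16), 15.0 ± 2.94 in SHR RVLM (n = 8) and 18.8 ± 1.03 in the 3 WKY RVLM pools with a usable raw Ct. The 4 unused raw columns that match a normalized column under another name had a median Ct of 14.2 to 16.7. They held 71, 44, 82 and 78 values, the numbers of assays detected in WKY RVLM pools 5, 6, 7 and 8. They most likely hold those pools, so the 3 pools used were most likely the latest of their group and do not stand for it. The WKY RVLM pools had the fewest assays detected. Their number of assays detected was lower than in SHR RVLM with an exact permutation p of 0.0522 (adjusted p 0.131 over 12 such comparisons), and the median Ct of the 3 pools was later than in WKY NTS with an exact permutation p of 0.0186 (adjusted p 0.131).

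**Figure D1:**
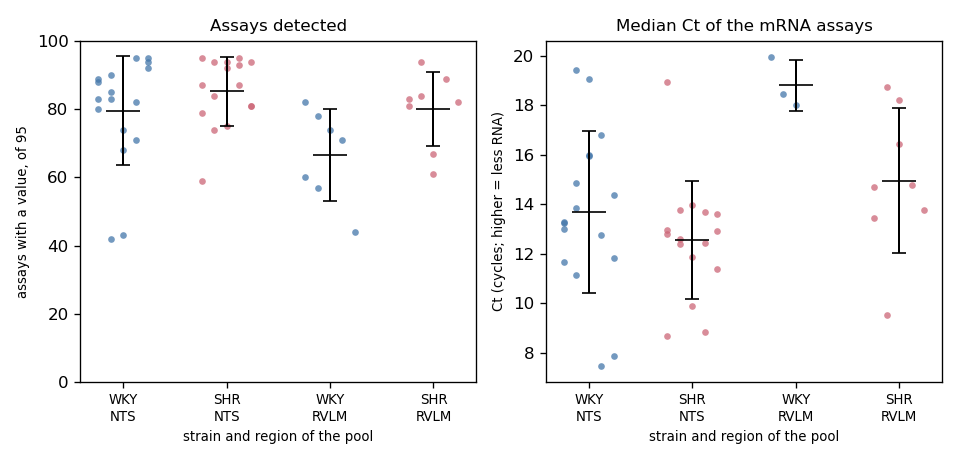
Number of assays detected (of 95) and median mRNA Ct in cycles for each of the 48 pools by strain and region; points are pools and bars are the mean ± SD. The WKY RVLM pools had 44 to 82 assays detected and, in 3 pools, a median Ct from 18.02 to 19.975.

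The comparison of SHR with WKY in the NTS addresses which microRNAs and mRNAs differ between neurons of the hypertensive and the normotensive strain. Il1a, which encodes the cytokine interleukin 1 alpha, had the smallest p. Its level was -5.31 ± 2.76 in SHR (SD, n = 16) and -1.88 ± 2.27 in WKY (n = 16), a difference of -3.43 ± 0.98 (SE) with an adjusted p of 0.0974, and 14 of 16 SHR pools lay below the WKY mean. The microRNAs that the study's protocol targets did not pass either. miR-376a was at 2.13 ± 4.48 in SHR and 0.37 ± 3.39 in WKY (n = 16 each), a difference of 1.76 ± 1.63 (adjusted p 0.616, permutation p 0.223), with 12 of 16 SHR pools above the WKY mean. miR-135a was at -0.85 ± 4.80 and -2.21 ± 6.10, a difference of 1.36 ± 1.77 (adjusted p 0.733, permutation p 0.498), with 8 of 16 SHR pools above the WKY mean. Relative to Actb both microRNA differences took the other sign, at -0.22 for miR-376a and -0.62 for miR-135a. With the Ct values past the last cycle counted as undetected, miR-135a differed by 0.22 (adjusted p 0.980).

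Of 95 assays tested in the NTS with limma, 0 passed the threshold, 8 had an unadjusted p under 0.05 (4 higher and 4 lower in SHR, where 4.75 would come by chance), and the permutation test also gave 0 past the threshold and 8 unadjusted. Lower estimates in SHR were those of the cytokine Il6 (-2.64 ± 1.11), the chemokine Ccl5 (-3.02 ± 1.36), the RNA sensor Tlr7 (-3.12 ± 1.42) and the interleukin 1 receptor antagonist Il1rn (-1.81 ± 0.98). Estimates above 0 were those of the interleukin 23 subunit Il23a (2.96 ± 1.29), the gamma-secretase subunit Ncstn (1.53 ± 0.73), the neuronal surface glycoprotein Cd200 (1.39 ± 0.67), the calcium-binding protein S100b (1.70 ± 0.84) and the 5-lipoxygenase activating protein Alox5ap (3.07 ± 1.58). Each of these 9 had an adjusted p of 0.525. Th, the rate-limiting enzyme of catecholamine synthesis, differed by -1.36 ± 1.41 (adjusted p 0.675), and the Rbfox3 assays, whose protein served to choose the cells, by 1.05 ± 0.71 and 1.30 ± 0.74. Without SHR NTS pool 10, SHR NTS pool 16 or WKY NTS pool 10, 1 assay, Il1a, passed, as it did with only pools of 9 to 14 cells. Pools share animals, so these p-values are too small.

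**Figure D2:**
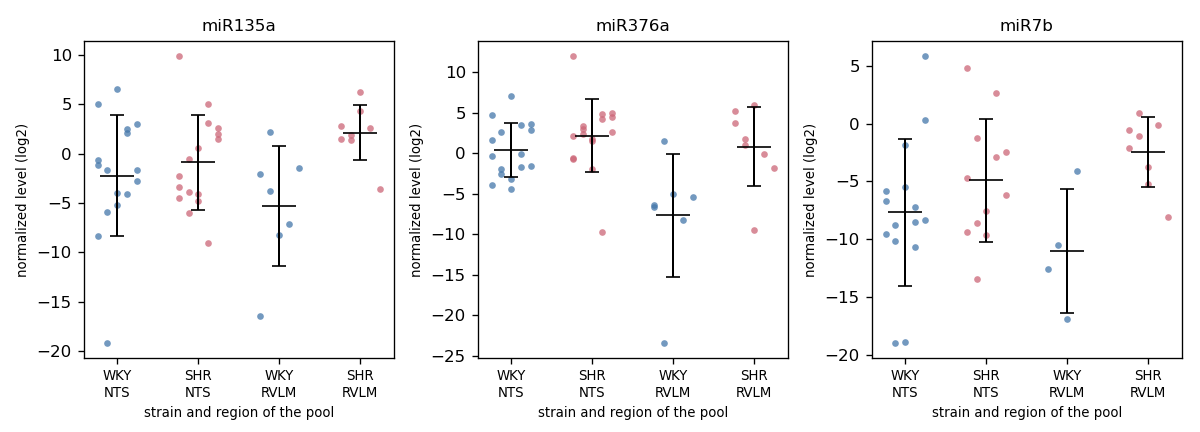
Normalized level (log2) of miR135a, miR376a and the assay named miR7b in each sample by strain and region; points are pools (WKY NTS pools 14 and 15 averaged) and bars are the mean ± SD. In the RVLM the mean of miR376a was 0.77 in SHR and -7.69 in WKY, where the lowest point comes from a Ct past the last cycle, while in the NTS it was 2.13 and 0.37.

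Among the gene lists in the NTS, 24 inflammation and eicosanoid assays split into 12 estimates above and 12 below 0. None passed over all assays, and 1, Il1a, passed when adjusted over the list alone (adjusted p 0.0246). The neuron marker list, in which 2 of 3 assays measure the selection marker Rbfox3, did not pass (1.05 ± 0.50, SE; permutation p 0.0351, adjusted p 0.211), and Syn1, a synaptic vesicle protein, was at 0.46 ± 0.52. The 3 microRNAs shifted by 2.14 ± 1.49 (adjusted p 0.388), and 0 of 3 passed when adjusted over the list alone, as did 0 of 2 study microRNAs. Of the catecholamine genes Dbh and Th 0 of 2 passed, with Dbh, which makes noradrenaline, at -2.52 ± 1.96. The same count of 0, over all assays and adjusted over the list alone, held for 5 glutamate genes such as Grm2 (-1.19 ± 0.73), 3 GABA genes such as Gad1, which makes GABA (0.31 ± 1.03), 4 neuropeptide genes such as Bdnf (-1.73 ± 1.04) and 4 renin-angiotensin genes such as Ace (0.65 ± 0.76). It also held for 3 immediate early genes such as cFos (1.38 ± 1.15), 3 oxidative stress genes such as Nos1 (-0.60 ± 0.87), 3 ion channel genes such as Cacna1d (1.01 ± 0.84), 5 second messenger genes such as Rgs2 (1.14 ± 0.84), and the reference assay Actb (1.49 ± 1.14). For markers of other cells, 0 of 2 astrocyte and 0 of 3 microglia markers passed, with Gfap at 0.02 ± 0.86, Aif1 at 1.36 ± 1.22, Itgam at -1.33 ± 1.35 and Cd68 at -1.66 ± 0.98. The lists' p-values over pools that share animals are too small as well.

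In the RVLM the strain comparison asks the same question in neurons of the pressor area. The microRNAs had the largest differences: miR-376a was at 0.77 ± 4.90 in SHR (SD, n = 8) and -7.69 ± 7.62 in WKY (n = 7), a difference of 8.46 ± 2.38 (SE, adjusted p 0.0706), with 7 of 8 SHR pools above the WKY mean. miR-135a was at 2.14 ± 2.82 and -5.28 ± 6.06, a difference of 7.42 ± 2.59 (adjusted p 0.168), with 8 of 8 SHR pools above the WKY mean. The assay named miR7b differed by 8.53 ± 3.15 (adjusted p 0.168). Taken as a list, the 3 microRNAs were higher in SHR by 8.53 ± 2.11, with an exact permutation p of 0.00109 and an adjusted p of 0.0131. Over all assays 0 of them passed, and 3 of 3 passed when adjusted over the list alone (smallest adjusted p 0.00258), with 2 of 2 for the study microRNAs. WKY RVLM pool 2 had the lowest miR-376a, at -23.50, from a Ct of 38.91 past the 30 cycles of the protocol. With that value counted as undetected the difference of miR-376a was 5.83 (adjusted p 0.167), and the list was higher by 7.04 ± 1.79 (exact permutation p 0.00171, adjusted p 0.0205). With only pools of at least 60 assays detected, which also left out pool 2, the list's shift was 7.68 with an adjusted p of 0.0559. With the microRNAs centred on their own median, which removes a shift they share, miR-376a differed by 0.45 and miR-135a by -0.60.

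Among the mRNAs of the RVLM, Stat3, a transcription factor downstream of interleukin 6 receptors, was at -1.10 ± 1.59 in SHR (n = 6) and -3.73 ± 1.51 in WKY (n = 5), a difference of 2.63 ± 0.79 (adjusted p 0.0806), with 5 of 6 SHR pools above the WKY mean. Further estimates above 0 were those of Cd200 (2.60 ± 0.98), the translation factor Eif4e (2.34 ± 0.94) and the cytokine lymphotoxin alpha, Lta (3.90 ± 1.62). Il1a (-3.70 ± 1.44), the tumour necrosis factor receptor Tnfrsf1b (-5.35 ± 2.07) and Ccl5 (-5.06 ± 2.10) were below 0, and all 6 had an adjusted p of 0.168. Th was at 0.49 ± 3.22 in SHR (n = 8) and -3.80 ± 5.56 in WKY (n = 5), a difference of 4.29 ± 2.20 (adjusted p 0.224), and the Rbfox3 assays differed by -0.24 ± 1.10 and -0.49 ± 1.14. In limma's test of 82 assays 0 passed, 20 had an unadjusted p under 0.05 (13 higher and 7 lower in SHR, with 4.1 by chance), and the permutation test gave 0 past the threshold and 15 unadjusted. Of 18 inflammation assays tested, 0 passed over all assays and 1, Stat3, adjusted over the list alone (adjusted p 0.0354). Astrocyte marker S100b differed by 2.81 ± 1.23 and microglia marker Cd68 by -2.85 ± 1.38 (adjusted p 0.170 and 0.202). The count was 3 without SHR RVLM pool 7, 1 without SHR RVLM pool 8, 2 without WKY RVLM pool 7 and 5 without WKY RVLM pool 8, always with miR-376a among them, and 7 with only pools of 9 to 14 cells. It was 6 without normalization and 17 with undetected values set to the last cycle, each with 3 WKY RVLM pools. With the median mRNA Ct as a covariate some assays kept fewer than 3 WKY RVLM pools, and no count is given. These p-values are too small because pools share animals.

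Detection itself was compared between the strains for assays found in some pools only. In the NTS 0 of 73 assays passed Fisher's exact test and 0 had an unadjusted p under 0.05, with 59 assays detected more often in SHR and 7 in WKY. For the RVLM 0 of 64 passed and 7 had an unadjusted p under 0.05. Hcrtr2, an orexin receptor, was detected in 7 of 8 SHR pools and 1 of 7 WKY pools (exact p 0.0101, adjusted p 0.328), and 57 assays were detected more often in SHR against 7 in WKY. With a Ct under 25 counted as detected, which left 3 WKY RVLM pools, it was 42 against 17, with 0 of 59 past the threshold, 10 unadjusted and a smallest adjusted p of 0.0596. Pools share animals, which makes these exact p-values too small.

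Whether the strain difference itself differed between the regions was tested as the NTS difference minus the RVLM difference. The interferon gene Ifng gave the smallest p, at -4.70 ± 1.69 (SE): its level was -2.63 ± 2.61 in SHR NTS (n = 16), -1.11 ± 2.91 in WKY NTS (n = 14), 0.39 ± 1.62 in SHR RVLM (n = 8) and -2.79 ± 3.50 in WKY RVLM (n = 7), with an adjusted p of 0.336. For miR-376a the value was -6.71 ± 2.88, for Lta -4.92 ± 2.0, for the glycolytic enzyme Ldha -2.93 ± 1.24, for the tight junction protein Ocln -3.13 ± 1.38, for Th -5.65 ± 2.61 and for neuropeptide Y, Npy, -3.16 ± 1.46. Above 0 were the neurotrophin receptor Ngfr (3.45 ± 1.53) and the potassium channel subunit Kcnd2 (2.31 ± 1.05), and Eif4e stood at -2.41 ± 1.15 (adjusted p 0.340). miR-135a gave -6.06 ± 3.14 (adjusted p 0.432), and the Rbfox3 assays 1.29 ± 1.31 and 1.79 ± 1.36. By limma 0 of 82 assays passed and 10 had an unadjusted p under 0.05 (2 above and 8 below 0, with 4.1 by chance). No permutation test was run for this contrast. Of the 2 study microRNAs 1, miR-376a, passed when adjusted over the list alone (adjusted p 0.0485), and over all assays 0 did, as did 0 of 3 in the list of all microRNAs (smallest adjusted p 0.0728). With the Ct past the last cycle counted as undetected, miR-376a gave -4.07 (adjusted p 0.480). The count was 10 with undetected values set to the last cycle. Sharing of animals between pools makes these p-values too small.

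The comparison of NTS with RVLM within WKY describes regional differences in the normotensive strain. Stat3 was higher in the NTS, at -0.47 ± 1.22 (SD, n = 12) against -3.73 ± 1.51 in the RVLM (n = 5), a difference of 3.26 ± 0.70 (SE, adjusted p 0.00277), and 12 of 12 NTS pools lay above the RVLM mean. miR-376a was higher in the NTS by 8.07 ± 2.08 (adjusted p 0.0135), at 0.37 ± 3.39 (n = 16) against -7.69 ± 7.62 (n = 7), with 16 of 16 NTS pools above the RVLM mean. That call rests on the value of WKY RVLM pool 2 with a Ct of 38.91, past the last cycle, and ended when it was counted as undetected (5.43, adjusted p 0.156). Gria3, a subunit of AMPA-type glutamate receptors, was higher by 3.56 ± 0.97 (adjusted p 0.0196), at 1.08 ± 1.23 (n = 12) against -2.48 ± 2.96 (n = 5), with 12 of 12 NTS pools above the RVLM mean. In limma's test 3 of 82 assays passed, all higher in the NTS, and 12 had an unadjusted p under 0.05 (8 higher and 4 lower). The permutation test gave 2 past the threshold, Stat3 (adjusted p 0.0133) and miR-376a (adjusted p 0.0189), with Gria3 at an adjusted p of 0.0839.

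Other estimates between the regions of WKY did not pass. Above 0 were S100b (2.93 ± 1.11), Cd200 (2.24 ± 0.85), the arginase Arg1 (4.11 ± 1.67) and the mitochondrial protein Cox7a2l (2.01 ± 0.84). Below 0 were the angiotensin II receptor Agtr1a (-3.17 ± 1.39) and Ptgr1, which degrades prostaglandins (-2.30 ± 1.01). Their adjusted p was 0.158 or 0.206. miR-135a differed by 3.07 ± 2.27 (adjusted p 0.553), Th by 1.79 ± 2.01 (adjusted p 0.704) and the Rbfox3 assays by 0.67 ± 0.95 and 0.64 ± 0.99. By list, 1 of 18 inflammation assays (Stat3), 1 of 4 glutamate assays (Gria3) and 1 of 3 microRNAs passed, both over all assays and adjusted over the list alone. S100b of 2 astrocyte markers passed only when adjusted over the list alone (adjusted p 0.0230). The call of Gria3 was lost without WKY RVLM pool 1 or 3 (2 assays passed), that of miR-376a without WKY RVLM pool 2 (difference 5.43, adjusted p 0.157), and relative to Actb only miR-376a passed. That last value (14.26, adjusted p 0.0188) came from raw Ct, so from 3 WKY RVLM pools, with pool 2 and its Ct past the last cycle among them. With the microRNAs centred on their own median, which removes what they share, miR-376a differed by 1.81 (adjusted p 0.548), and with only pools of at least 60 assays detected by 5.77 (adjusted p 0.125). The latter limit also left out WKY RVLM pool 2, with 57 assays detected. Cd200 joined without WKY NTS pool 12 or WKY RVLM pool 8 and S100b without WKY NTS pool 8 (4 assays each). The count was 17 without normalization and 20 with undetected values set to the last cycle, each with 3 WKY RVLM pools. Of the 3 calls only miR-376a was among the 17 and among the 20. With the median mRNA Ct as a covariate all 3 kept their direction, at 3.57 for Stat3, 5.28 for Gria3 and 12.01 for miR-376a. Stat3 and Gria3 had fewer than 3 WKY RVLM pools there, and miR-376a held the value of pool 2, so no count is given for that setting. Without normalization Stat3 and Gria3 had too few values to be tested. At the last cycle Stat3 was at 2.48 (adjusted p 0.415) and Gria3 at 4.41 (adjusted p 0.166). Pools share animals, so these p-values are too small.

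**Figure D3:**
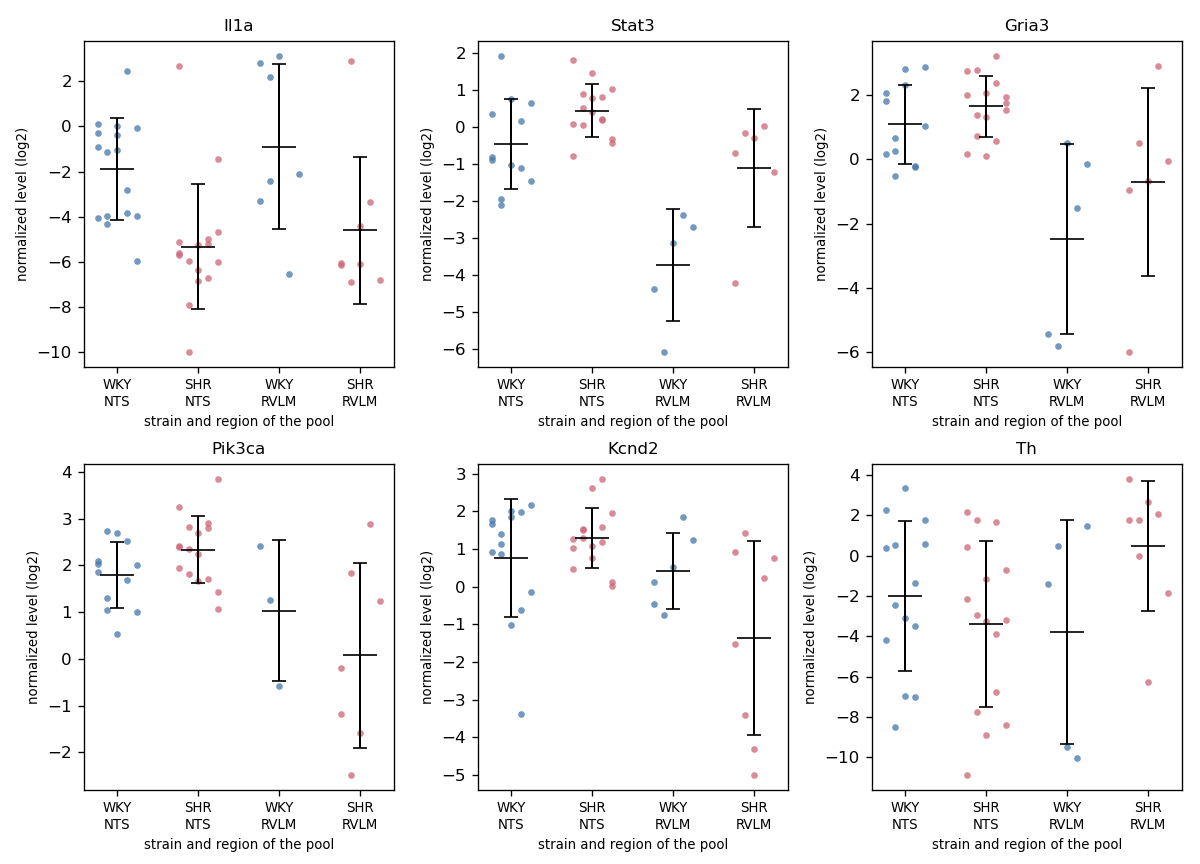
Normalized level (log2) of Il1a, Stat3, Gria3, Pik3ca, Kcnd2 and Th in each sample by strain and region; points are pools (WKY NTS pools 14 and 15 averaged) and bars are the mean ± SD. Stat3 stood at a mean of -0.47 in WKY NTS and -3.73 in WKY RVLM, and Pik3ca at 2.34 in SHR NTS and 0.07 in SHR RVLM.

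Within SHR, the same comparison describes regional differences in the hypertensive strain. Pik3ca, a catalytic subunit of phosphoinositide 3-kinase, was higher in the NTS, at 2.34 ± 0.72 (SD, n = 16) against 0.07 ± 1.97 in the RVLM (n = 7), a difference of 2.26 ± 0.58 (SE, adjusted p 0.0224), with 16 of 16 NTS pools above the RVLM mean. Kcnd2, a subunit of A-type potassium channels, was higher by 2.65 ± 0.70 (adjusted p 0.0224), at 1.29 ± 0.80 (n = 15) against -1.36 ± 2.57 (n = 8), with 15 of 15 NTS pools above the RVLM mean, while relative to Actb its difference was -0.45. With WKY NTS pools 14 and 15 averaged, 2 of 91 assays passed limma's test. With all 48 pools counted, as first planned, 5 passed, because the calcium channel Cacna1d (adjusted p 0.0496), the cyclooxygenase Ptgs2 and the G-protein regulator Rgs3 joined Pik3ca and Kcnd2. In the averaged fit those 3 had an adjusted p of 0.0564, with differences of 3.21 ± 1.00, 5.08 ± 1.57 and 2.62 ± 0.83. An unadjusted p under 0.05 was found for 27 assays (20 higher and 7 lower in the NTS). The permutation test gave 6 past the threshold, which were Pik3ca, Kcnd2, Ptgs2 (adjusted p 0.0407) and, at an adjusted p of 0.0357, Stat3, Il10 and Ldha.

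Further estimates in SHR that did not pass limma's test, among them Ldha and Il10 that passed the permutation test, were the activity marker cFos at 4.60 ± 1.49 (adjusted p 0.0601), Gria3 at 2.35 ± 0.88, Ldha at -2.04 ± 0.76, the anti-inflammatory cytokine Il10 at -2.56 ± 0.97 and Ifng at -3.02 ± 1.15 (adjusted p 0.102 each). Th was at -3.37 ± 4.11 in the NTS (n = 16) and 0.49 ± 3.22 in the RVLM (n = 8), a difference of -3.86 ± 1.67 (adjusted p 0.137), with 13 of 16 NTS pools below the RVLM mean. miR-135a differed by -2.99 ± 2.17 (adjusted p 0.379) and miR-376a by 1.36 ± 1.99 (adjusted p 0.621). Of the neuron markers 0 passed over all assays, with Syn1 at 1.51 ± 0.62 (adjusted p 0.119) and Rbfox3 at 1.95 ± 0.89 and 2.43 ± 0.93. Of the 3 of 3 past the threshold when adjusted over the list alone, 2 measure Rbfox3, by whose protein the cells were chosen, and are not read as a finding. Syn1, which was not used to choose cells, passed there as well (adjusted p 0.0278), but not over all assays. Of the ion channel genes 1 of 3 passed over all assays, and 3 of 3, with Kcnip2 at 1.52 ± 0.70, when adjusted over the list alone. Of 5 second messenger genes 1 passed over all assays and 2, Pik3ca and Rgs3, adjusted over the list alone, and of 3 immediate early genes 0 and 1 (cFos, adjusted p 0.0119). The count was 0 without SHR RVLM pool 7 or 8, 1 without SHR RVLM pool 3 or 4, 3 without pool 6, 6 without pool 2 and 9 without pool 5 of that group, and 6 and 4 without SHR NTS pools 12 and 16. It was also 0 relative to Actb, with log2 cell number or median mRNA Ct as a covariate, with only pools of 9 to 14 cells and with undetected values set to the last cycle, and 9 with at least 60 assays detected. With cell number as a covariate the differences of Pik3ca and Kcnd2 were 1.90 and 2.46 (adjusted p 0.106), and in pools of 9 to 14 cells 1.88 and 2.32 (adjusted p 0.0732), so their size changed little there. With the median mRNA Ct they were 1.91 and 1.54 (adjusted p 0.0938 and 0.230), at the last cycle 3.07 and 0.99, and relative to Actb Pik3ca was at 0.90. The SHR RVLM pools had a later median Ct than the SHR NTS pools (15.0 against 12.5, permutation p 0.0425, adjusted p 0.131) and fewer cells (10.25 against 12.9, permutation p 0.0548, adjusted p 0.131). Pools share animals, so the p-values are too small.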

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

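The test of microglia markers against Il1a, the tests that use the median mRNA Ct or the number of assays detected as a covariate and the test on the microRNA constant were chosen after the main results had been seen. What each would show was written down before it was run, except for the microglia test, whose criterion was rewritten after its first result.

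Lower Il1a in SHR than in WKY pools of the NTS was -3.43 (95% interval -5.45 to -1.41 without moderation of the variance). A first candidate explanation is that the Il1a signal does not follow the RNA content of a pool, so that dividing by the median mRNA would lower it in pools with more RNA. With the median mRNA Ct as a covariate the difference was -2.75 (-4.49 to -1.02), more than the size this explanation would leave, although on the raw Ct scale the interval of the difference reached 0 (1.92 cycles later in SHR, -0.05 to 3.89). A second is fewer microglia in the SHR pools, although cells were captured by a neuronal Rbfox3 stain: the mean of Aif1, Itgam and Cd68 differed by -1.12 (-2.90 to 0.65), and Il1a minus that mean still differed by -2.31 (-4.54 to -0.07), an interval that only just leaves out 0. A strain difference in the neurons stays open and untested, and 0 of 95 assays passed in this comparison, so the pattern remains a hypothesis.

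Higher miR-376a and miR-135a in SHR than in WKY pools of the RVLM came to 7.94 as the mean of both (3.43 to 12.45), and to 6.43 (2.37 to 10.50) without a miR-376a value from a Ct past the last cycle. The WKY RVLM pools had the fewest assays detected, and with that number as a covariate the mean was 7.51 (2.76 to 12.26). The number of assays detected thus did not account for the difference, but it is a rough measure of RNA content. SHR RVLM pool 7 and SHR NTS pool 2 had 84 assays detected each, at a median Ct of 18.73 and 12.58. RNA content therefore stays open. Relative to the mRNA median the mean was 10.93 (5.07 to 16.78) against 9.64 in the same 43 samples, so it was not smaller on that scale. Only 3 of them were WKY RVLM, with a later Ct than the unused raw columns. Both means also hold the miR-376a value of WKY RVLM pool 2 from a Ct past the last cycle, and this fit was not run without it. The separate microRNA constant therefore stays open as a cause. A shift shared by all 3 microRNAs, such as a difference in recovery of small RNA, may remain. With the microRNAs centred on their own median miR-135a differed by -0.60. That centring removes any shift they share, so it cannot tell recovery from a strain difference in all 3. Strain remains open as well.

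Higher Stat3, Gria3 and miR-376a in NTS than in RVLM pools of WKY came to 5.58 as their mean (2.75 to 8.41), and to 4.14 (1.59 to 6.70) without the miR-376a value of pool 2 from a Ct past the last cycle, which ended the call of miR-376a (8.07 to 5.43, adjusted p 0.156). With the number of assays detected as a covariate it was 5.39 (2.40 to 8.38), so that number did not account for the mean. Because it is a rough measure of RNA content, RNA content itself stays open. With only pools of at least 60 assays detected miR-376a fell to 5.77 from 8.07 (adjusted p 0.125) and its call ended. This limit also left out WKY RVLM pool 2, with 57 assays detected. Without the value of that pool alone the difference was already 5.43. Because that pool also had few assays detected, the fall cannot tell RNA content from its value past the last cycle. For Gria3 alone the covariate ended the call, at 2.97 against 3.56, with an SE of 1.08 against 0.95 and an adjusted p of 0.204, so the lower estimate and the larger error both contributed. A regional difference between the neurons stays open and untested.

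Regrouping at random gave the following counts, with 100 splits per comparison and the real one among them. Where the real count was 0 every split reaches it, so 100 of 100 was certain for the strains in the NTS (highest other 1), the strains in the RVLM (highest other 21) and the difference of strain differences (highest other 7), and these splits say nothing about chance. The split with 21 assays may reflect a structure of the pools, which was not tested. Between the regions of WKY 2 of 100 splits gave at least 3 assays (highest other 5), and between those of SHR 1 of 100 gave at least 2 (highest other 1). Both shares were under 0.05, but chance is not excluded, because pools that share animals are not independent. The WKY count includes miR-376a, whose call rests on a Ct past the last cycle. In SHR the count was 5 with all 48 pools and 0 without SHR RVLM pool 7 or 8. The splits were not redone for these cases.

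A single pool stood far from the rest of its RVLM group in 10 of 69 sets of 4 to 10 values, against 3.45 by chance. In SHR RVLM pool 7, Il1a was at 2.90 (others -6.88 to -3.36), Stat3 at -4.22 (others -1.23 to 0.01) and Eif4e at 6.87 (others 3.23 to 4.65). In SHR RVLM pool 8, Ncstn was at -6.13 (others 0.38 to 1.92) and Rbfox3 assay A073 at -7.55 (others -0.30 to 3.97), and in SHR RVLM pool 6 Ngfr was at -11.65 (others -2.70 to 1.89). WKY RVLM pool 2 had miR-376a at -23.50 (others -8.26 to 1.44; a Ct of 38.91, past the 30 cycles run), pool 3 Eif4e at -4.99 (others 2.38 to 3.62) and pool 7 Ngfr at -3.36 (others 0.08 to 2.61). In WKY RVLM pool 6, Cox7a2l was at -7.15 (others -1.06 to 2.08).

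Of 5 raw columns that entered no comparison, 1 matched no normalized column and held Ct values for 20 assays with a median of 24.6. The other 4 matched a normalized column under another name and held 44 to 82 values with a median from 14.2 to 16.7.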

How the results depend on the processing

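The limit to at least 60 assays detected, the covariates for assays detected and median mRNA Ct, the microRNAs relative to the mRNA median, the Ct past the last cycle counted as undetected and the changes to the close pools were chosen after seeing the data. Over the named assays other than miR-135a and miR-376a in the NTS, 1438 values under alternatives were compared with the main ones: 1297 kept direction and side of the threshold, 72 newly passed, 29 no longer passed and 40 reversed. Where a value below moved, the cause was not tested unless stated.

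For the strains in the NTS the count of 0 became 1, Il1a, with centring on assays detected in every pool, with log2 cell number as a covariate, with pools of 9 to 14 cells, with only the groups compared in the fit and with at least 60 assays detected, and ranged from 0 to 1 when 1 pool was left out. Il1a's adjusted p ran from 0.00666 to 0.438 over these and the other alternatives. miR-135a reversed relative to Actb (-0.62), in pools of 9 to 14 cells (-0.16) and with at least 60 assays detected (-0.70), and miR-376a relative to Actb (-0.22). For the strains in the RVLM the count of 0 became 1 with centring on assays detected in every pool, 6 without normalization (6 higher, 0 lower, on 49 assays tested), 1 relative to Actb, 17 with undetected values at the last cycle (14 higher, 3 lower), 7 in pools of 9 to 14 cells, 2 with only the groups compared, 19 with the median mRNA Ct as a covariate (6 higher, 13 lower) and 1 with microRNAs relative to the mRNA median. It ranged from 0 to 5 when 1 pool was left out. The assay that passed with centring, relative to Actb and relative to the mRNA median was miR-376a. Its values there rest on 3 WKY RVLM pools, with pool 2 and its Ct past the last cycle among them. The last-cycle setting replaces undetected values and so turns detection into level. The 1 list shift in the RVLM became 0 with at least 60 assays detected (adjusted p 0.0559) and with centring on assays detected in every pool, where fewer WKY pools had a value and the microRNA list could not be tested.

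The count of 0 for the difference of strain differences became 1 with centring on assays detected in every pool, without normalization, relative to Actb and in pools of 9 to 14 cells, 10 with undetected values at the last cycle and 12 with the median mRNA Ct as a covariate. It stayed 0 with any pool left out. Where it was 1, the assay was miR-376a, which outside the pools of 9 to 14 cells rested on the same 3 WKY RVLM pools. Between the regions of WKY the count of 3 became 17 without normalization (17 higher, 0 lower), 1 relative to Actb and 20 at the last cycle (16 higher, 4 lower). Of the 3 calls of the main fit only miR-376a was kept without normalization, relative to Actb and at the last cycle. The count was 2 with microRNAs on their own median (miR-376a 1.81, adjusted p 0.548), 2 with only the groups compared (Gria3 adjusted p 0.0759), 2 with at least 60 assays detected (miR-376a 5.77, adjusted p 0.125) and 2 with a Ct past the last cycle counted as undetected (miR-376a 5.43, adjusted p 0.156). With the number detected as a covariate it stayed 3, but Araf, lower in the NTS, stood in place of Gria3. It ranged from 2 to 4 with 1 pool left out. Between the regions of SHR the count of 2 became 1 without normalization, 0 relative to Actb, 0 at the last cycle, 0 with log2 cell number, 0 in pools of 9 to 14 cells, 4 with only the groups compared (3 higher, 1 lower), 9 with at least 60 assays detected, 1 with the number detected and 0 with the median mRNA Ct as a covariate. It was 5 with the close WKY NTS pools counted separately, 6 without SHR NTS pool 14 and SHR RVLM pool 2, 6 by the permutation test and from 0 to 9 with 1 pool left out.

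Scalings moved the median of all assays, which in the main fit was 0.13 (strains, NTS), -0.10 (strains, RVLM), 0.40 (regions, WKY) and 0.47 (regions, SHR). Without normalization it was 1.22, 2.31, 4.11 and 2.81, and relative to Actb -1.36, -0.12, -0.23 and -1.85. With centring on assays detected in every pool it was 0.31, 0.07, 1.07 and 0.97.

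Without normalization these reversed: Il1rn (0.0821) and Th (0.0652) for the strains in the NTS, the Rbfox3 assays for the strains in the RVLM (4.5 and 4.28), Kcnd2 (-0.82) and the Rbfox3 assays (-2.30 and -1.83) for the difference of strain differences, and Ldha (0.36) and Il10 (0.27) between the regions of SHR. Relative to Actb these reversed: Ncstn (-0.0663), Cd200 (-0.11), S100b (-0.25) and the Rbfox3 assays (-0.79 and -0.54) for the strains in the NTS, Kcnd2 (-0.34) for the difference of strain differences, and Kcnd2 (-0.45) and miR376a (-2.35) between the regions of SHR. With the microRNAs on their own median, which removes what they share, miR135a reversed for the strains in the RVLM (-0.60), the difference of strain differences (0.71) and the regions of WKY (-3.19), and miR376a for the difference of strain differences (0.0690). With undetected values at the last cycle these reversed: Alox5ap (-1.86) for the strains in the NTS, and Rbfox3 (-0.39 and -0.37) and Th (-0.98) between the regions of WKY. Rbfox3 assay A048 reversed for the strains in the RVLM with centring on assays detected in every pool (0.15) and with the median mRNA Ct (0.14). Both Rbfox3 assays reversed there in pools of 9 to 14 cells (0.75 and 0.85) and with 1 pool left out, where A048 ran from -0.941 to 0.73 and A073 from -1.11 to 0.83. Between the regions of WKY the Rbfox3 assays reversed with at least 60 assays detected (-0.0689 and -0.0246), and A048 with 1 pool left out, where it ran from -0.0377 to 1.31. The median mRNA Ct reversed Arg1 (-1.40), Cox7a2l (-0.38) and Th (-1.57) between the regions of WKY. miR376a between the regions of SHR reversed with log2 cell number (-0.21), in pools of 9 to 14 cells (-1.28) and with 1 pool left out (from -0.10 to 2.16).

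Replicate numbers were checked for pairing: the mean correlation of same-numbered pools' deviations from their group means lay between -0.10 and 0.01 for the 6 pairs of groups, so the numbers do not pair pools. With the replicate number as a block the counts were 0 in each of the 5 comparisons, against 3 between the regions of WKY and 2 between those of SHR without it. The estimates under it were 3.51 for Stat3, 8.00 for miR-376a and 2.85 for Gria3 in WKY and 2.25 for Pik3ca and 3.01 for Kcnd2 in SHR. With it miR-135a and miR-376a differed between the strains in the NTS by 1.24 and 1.65.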

Other observations

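SHR NTS pool 14 and SHR RVLM pool 2, which the labels place in different regions, differed with a robust SD of 0.267 cycles (SD 0.704) over 91 assays, less than the smallest value, 0.623, among the within-group pairs other than WKY NTS pools 14 and 15. Both were kept. Without them 6 assays differed between the regions of SHR, among them the 2 found with them.

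Assays differed in how their raw Ct followed the median mRNA Ct of a pool, which was not part of any comparison. Across the 39 to 44 pools with a Ct the slope was 0.43 ± 0.14 (SE) for Il1a, 0.26 ± 0.05 for Ptgr1 and 0.32 ± 0.04 for Grm2, and for the glial markers S100b and Gfap it was 1.64 ± 0.11 and 1.55 ± 0.10. Syn1 had 1.17 ± 0.08 and miR376a 1.29 ± 0.27. Of the mRNAs called between regions, Stat3 had 1.42 ± 0.08 and Gria3 1.51 ± 0.11 (36 pools each). Pik3ca had 1.23 ± 0.08 (36 pools) and Kcnd2 1.36 ± 0.08 (41 pools). Pools share animals, so these errors are too small. A slope above 1 raises the normalized value in pools with an earlier median Ct. NTS pools had the earlier one (12.5 against 15.0 in SHR, 14.1 against 18.8 in WKY with 3 RVLM pools, most likely the latest of their group). The fit with the median mRNA Ct as a covariate bears on this. Between the regions of SHR it left smaller differences for Pik3ca and Kcnd2, given above. Between those of WKY it gave 3.57 for Stat3 and 5.28 for Gria3, but from fewer than 3 WKY RVLM pools. The slopes also hold group differences, so how much of these calls follows from them stays open.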
